A study of Homo sapiens with 16 samples.

How the data were processed

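The series holds 16 Affymetrix PrimeView expression arrays of total RNA from Nalm6, a human B-cell precursor acute lymphoblastic leukaemia cell line. Per the labels, the cells were either control cells or cells said to overexpress active CASP1, and were either left untreated or given prednisolone, a synthetic glucocorticoid, for 24 hours, with 4 arrays in each of the 4 groups. The treatment is spelled as a form of prednisone in the sample labels and as prednisolone in the labels' protocol; prednisolone is used here, and the dose is not given in the sources used here. Per the labels' protocols, cells grew in RPMI1640 medium with serum and glutamine, RNA was taken with a phenol-based reagent and the target was labelled with biotin. The deposited values are log2 probe set signals made by the authors with RMA, per the submitters' processing notes; the software, its version and the probe set definition are not given in the sources used here. RMA brings arrays to a common scale, so differences in total RNA per cell were not measured.

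The deposited table had 49395 probe sets and 16 columns, and 0 columns belonged to no sample. Array medians lay between 4.85 and 4.93 on the log2 scale, and no further normalization was made for the tests. For arrays, the number of arrays limits the precision. Probe sets were named from the platform annotation, in which 44988 probe sets had 1 gene, 1832 had several, 2473 had none and 102 were controls. Gene symbols were compared by Entrez identifier with the RefSeq gene table of the human genome, which held 99.94% of them, and 0 symbols were updated. Of the probe sets with 1 gene, the one with the highest mean over all 16 arrays stood for its gene, which gave 18132 genes, 6398 with a single probe set and 11734 with several. Probe sets with several genes or none were not used for the tests of genes.

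Each gene was fitted with limma 3.58.1 under R 4.3.3, with 4 group means and all 16 arrays in 1 model, which left 12 residual degrees of freedom, and the moderated two-sided test (eBayes, no trend, not robust) added 5.46 prior degrees of freedom. The median residual SD was 0.167 on the log2 scale. The comparisons were prednisolone against untreated in control cells, prednisolone against untreated in cells labelled CASP1, cells labelled CASP1 against control cells without and with prednisolone, and the interaction, which is the prednisolone response in cells labelled CASP1 minus that in control cells. P-values were adjusted by Benjamini and Hochberg over all 18132 genes in each comparison, and a gene was called at an adjusted p under 0.05. Every adjusted p in the text is from limma unless a permutation is named. The labels do not say that arrays came from separate cultures, so p-values measure only the spread between these samples.

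The 26 gene lists named 717 genes, of which 662 were measured. Each list was tested in each comparison with limma's camera, which compares its genes with all others, with a preset correlation of 0.01 between genes and adjustment over the 26 lists, and again with a correlation estimated from the data. The lists covered glucocorticoid-induced genes, the MYC and nucleolar programme, DNA replication, mitosis, p53 targets, the BCL2 family, the inflammasome, NF-kappaB and interferon targets, antigen presentation, pre-B cell and plasma cell identity, lipid, energy and amino acid metabolism, ribosomal proteins, chaperones, autophagy and FOXO targets, histones, MAPK feedback and markers of other cell types. Counts of called members are given over all genes and adjusted over the list alone. Of the 130 list tests, 24 had a mean, a median and a direction of the test that differed in sign, and 0 of these 24 were called.

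The size of the prednisolone response was compared between the lines with a response ratio. Genes were selected as called for prednisolone in control cells on the arrays of 2 replicate numbers, and on the other 2 numbers the mean response in cells labelled CASP1, signed by the selection, was divided by that in control cells. The median and the range over the 6 choices of numbers are given. The overlap of calls between comparisons was set against that of independent lists. Because none of the arrays of the first prednisolone comparison are in the second, these overlaps share no arrays, and the same holds for the 2 comparisons between the lines.

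The named genes followed a rule. CASP1 and NR3C1 came first. Next came the 12 genes with the largest rise and the 12 with the largest fall among genes called whose groups did not overlap, with 6 and 6 for the comparison of treated cells and no condition on overlap for the interaction. Placeholder symbols were passed over, and each list gave up to 4 members with the largest absolute difference. Genes outside the rule are marked as chosen after their values were seen. The comparisons, tests, gene lists, naming rule and most alternatives were chosen before the data were examined.

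The alternatives were quantile normalization of the arrays again, centring each array on its 75th percentile, leaving out the dimmest 30% or 50% of genes, the mean of a gene's probe sets, every probe set on its own, trend and robust settings, array weights, the groups of a comparison alone, a replicate block, an adjusted p under 0.01, a change of at least 1.5-fold, other gene selections for the ratio and leaving out each array. Leaving out the 4 arrays numbered 1 together, and a batch term for them, were chosen after seeing the data. Raw array files were not analysed here.

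The procedure was tested on simulated data built on the residual spread of these arrays, with 50 genes changed at each of several sizes. At a log2 change of 1, between 94% and 96% of changed genes were recovered in the simple comparisons and 90% in the interaction. At 0.5, the shares were 58% to 60% and 22%. False calls made up 4.3% to 6.67% of all calls. A response ratio of 0.6 put in came back as 0.613, and of the lists 1 was moved and called, with 0 others called. The simulated noise was independent between genes, without a shift of the replicate 1 arrays, and the same genes responded in both lines. The simulation therefore could not test the preset correlation of the lists or the bias from selecting genes in control cells.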

Results

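Gene expression was measured on 16 arrays of Nalm6, a B-cell precursor acute lymphoblastic leukaemia line, in a design of 2 lines by 2 treatments with 4 arrays in each group. The lines were control cells and cells labelled as overexpressing active CASP1, the inflammatory caspase that matures interleukin 1 beta. Each line was left untreated or given prednisolone for 24 hours. The series title names the question, which is whether CASP1, by cleaving the glucocorticoid receptor, makes leukaemia cells resistant to glucocorticoids. On each array 49395 probe sets gave log2 signals between 1.69 and 14.28, and 18132 genes were tested. The correlation between arrays of a group ranged from 0.9832 to 0.9973 across probe sets. Replicate 1 of each group stood apart from the other 3 arrays, as described with the counts it changed.

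The gene named in the labels was lower, not higher, on the arrays labelled CASP1. CASP1 signal was 7.75 ± 0.15 (SD, n = 4) in untreated control cells and 5.69 ± 0.25 in untreated cells labelled CASP1. With prednisolone it was 6.95 ± 0.097 in control cells and 5.02 ± 0.26 in cells labelled CASP1. The difference was -2.06 (SE 0.13), a 4.16-fold lower signal, in untreated cells (adjusted p = 2.3e-08) and -1.93, or 3.82-fold lower, in treated cells (adjusted p = 5.1e-08). Of the 9 CASP1 probe sets, 7 were called lower in untreated cells, by -1.7 to -2.19, and the 2 others were near the lowest signals of the arrays, with group means up to 2.746. The positions of these probes on the introduced construct are not given in the sources used here, so the arrays cannot show whether introduced RNA was present. Directions between the lines therefore follow the labels, and the label goes against the CASP1 signal in each of them. CASP1 also fell with prednisolone in both lines, with a change of -0.80 in control cells (adjusted p = 0.00037) and of -0.67 in cells labelled CASP1 (adjusted p = 0.0045).

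NR3C1, which encodes the glucocorticoid receptor, had nearly equal signal in the untreated lines, at 10.18 ± 0.17 in control cells and 10.15 ± 0.13 in cells labelled CASP1 (difference -0.03, adjusted p = 0.92). It rose with prednisolone by 1.24 (SE 0.098) in control cells and by 0.85 in cells labelled CASP1, with adjusted p = 7.3e-08 and 1.7e-05, and all 10 of its probe sets rose in mean signal in both lines. In treated cells NR3C1 was lower on the arrays labelled CASP1 by -0.42 (adjusted p = 0.0059), but the test of the difference between the 2 responses gave -0.39 with adjusted p = 0.27. The arrays measure RNA, so cleavage of the receptor protein was not measured.

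**Figure D1:**
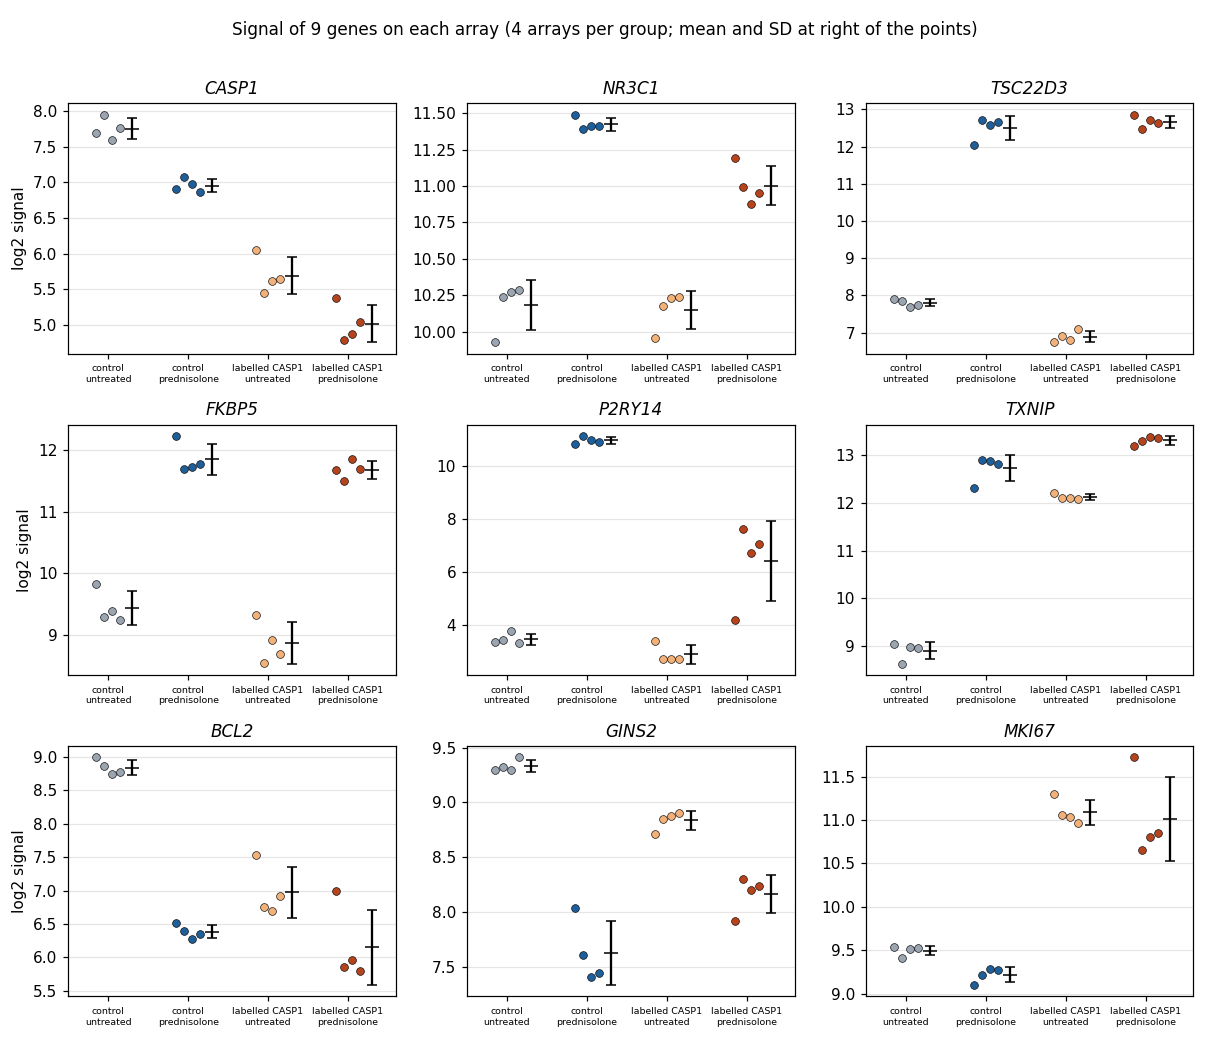
Log2 signal (y axis) of 9 genes on each of the 16 arrays (points), by group (x axis), with the mean and SD of the 4 arrays at the right of the points. CASP1 was lower on the arrays labelled CASP1 (5.69 against 7.75 in untreated cells), TSC22D3 rose by 4.70 and 5.79 with prednisolone in control cells and cells labelled CASP1, and P2RY14 rose by 7.49 and 3.51.

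Prednisolone changed the control cells widely, and the largest changes included well-known targets of the receptor. TSC22D3, which encodes the glucocorticoid-induced leucine zipper protein, rose 26-fold (log2 4.70, SE 0.13, n = 4, adjusted p = 1.4e-13). P2RY14, a receptor for UDP-sugars, rose 180-fold (log2 7.49, SE 0.47), from a signal near the floor. TP53INP1, a p53-inducible regulator of cell death and autophagy, rose 34.2-fold, KLF2, a quiescence factor of lymphocytes, 21.2-fold, and TXNIP, an inhibitor of glucose uptake, 14.2-fold. The immune receptors LILRA2 and LILRB2 rose by 4.37 and 4.20, and PRDM1, a driver of plasma cell differentiation, by 3.91. BCL2, which protects cells from apoptosis, had the largest fall, at -2.46 (SE 0.21, 5.49-fold, adjusted p = 2.3e-07). Its opponents BMF and BCL2L11 rose by 2.04 and 1.21. Other falls were in UNG, a DNA repair enzyme, at -2.11, ID3, an inhibitor of B-cell transcription factors, at -2.04, IL1B, which encodes interleukin 1 beta, at -1.97, and SKP2, which marks cell cycle inhibitors for degradation, at -1.73.

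The fixed lists moved in groups in control cells. Of the 44 measured glucocorticoid-induced genes, 24 rose and 3 fell over all genes, and 27 rose and 3 fell adjusted over the list alone (mean log2 1.10, adjusted p = 5.67e-25). FKBP5, a co-chaperone that curbs the receptor, rose by 2.42 and NFKBIA, the inhibitor of NF-kappaB, by 1.56. Of 39 DNA replication and S phase genes, 36 fell and 0 rose, and 37 fell adjusted over the list alone (mean -0.965, adjusted p = 4.88e-43), among them GINS2 at -1.70 and MCM10 at -1.48. Of 35 genes of MYC and nucleolar ribosome biogenesis, 22 fell and 0 rose, and 27 fell adjusted over the list alone (mean -0.485, adjusted p = 9.44e-16), with MYC at -1.12. In antigen presentation, 15 of 23 genes rose and 1 fell (17 and 1 adjusted over the list alone, mean 0.782, adjusted p = 7.95e-13), including HLA-DMB at 2.17 and CIITA, the master regulator of class II genes, at 2.01. Of 29 autophagy and FOXO target genes, 14 rose and 1 fell (17 and 1 adjusted over the list alone, mean 0.729, adjusted p = 8.21e-13). Endoplasmic reticulum stress chaperones rose in 6 of 21 cases and fell in 1, as adjusted over the list alone (mean 0.219, adjusted p = 0.000178), with HSPA5, the main chaperone of that compartment, at 0.65. Cholesterol biosynthesis had 2 rising and 12 falling genes of 24 (2 and 13 adjusted over the list alone, mean -0.254, adjusted p = 0.000524), with HMGCS1 at -0.88 and LSS at 1.56. These 7 lists also passed with an estimated correlation.

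Another 5 lists passed in control cells only with the preset correlation. Of 35 genes of G2 and mitosis, 11 fell and 0 rose (17 falling adjusted over the list alone, mean -0.332, adjusted p = 1.07e-08, and adjusted p = 0.191 with an estimated correlation), with CCNA2 at -0.73. Of 28 respiratory chain genes 4 fell, as adjusted over the list alone (mean -0.157, adjusted p = 0.00434, and adjusted p = 0.302 with an estimated correlation), and the call ended when the arrays were quantile normalized again (-0.105, adjusted p = 0.085). ATF4 and amino acid response genes had 12 of 33 falling and 1 rising (17 and 1 adjusted over the list alone, mean -0.329, adjusted p = 7.11e-05, and adjusted p = 0.568 with an estimated correlation), with PHGDH, an enzyme of serine synthesis, at -0.77. This mean was -0.15 without replicate 1 of the untreated control cells and -0.128 without the 4 arrays of replicate 1. Of 27 glycolysis and hypoxia genes 5 fell, as adjusted over the list alone (mean -0.253, adjusted p = 0.0214, and adjusted p = 0.785 with an estimated correlation), with PKM at -0.98. This mean was -0.0922 without replicate 1 of the treated control cells, -0.438 without replicate 1 of the untreated ones, and -0.198, -0.19 and -0.188 without untreated replicates 2, 3 and 4, and adjusted p was over 0.05 in all of these but the second. Without the 4 arrays of replicate 1 together it was -0.277 with adjusted p = 1.4e-05. Heat shock and receptor chaperones had 7 of 18 falling and FKBP5 the only one rising (8 falling adjusted over the list alone, mean -0.113, adjusted p = 0.0489, and adjusted p = 0.267 with an estimated correlation). That call ended without any 1 of 5 arrays, which were untreated replicates 2, 3 and 4 and treated replicates 1 and 3, with means of -0.101, -0.109, -0.106, -0.0873 and -0.115. It was kept without the 4 arrays of replicate 1 together (-0.112, adjusted p = 0.016). It also ended when the arrays were quantile normalized again (-0.074), centred on the 75th percentile (-0.0962), without the dimmest 30% of genes (-0.122) and with the mean of each gene's probe sets (-0.078).

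In limma's test, 2568 of 18132 genes were called for prednisolone in control cells, 1039 higher and 1529 lower, and 242 of them were at least 2-fold higher and 122 at least 2-fold lower. Leaving out the 4 arrays of replicate 1 together, a choice made after seeing the data, raised the count to 3969.

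In cells labelled CASP1, where CASP1 signal was the lower one, known receptor targets also rose with prednisolone. TSC22D3 had the largest rise, 55.2-fold (log2 5.79, SE 0.13, n = 4, adjusted p = 4.1e-15), and FKBP5 rose by 2.80. LILRA2 rose by 4.06, PRDM1 by 3.82, P2RY14 by 3.51 (11.4-fold, SE 0.47, adjusted p = 7.6e-05, with an SD of 1.5 between the 4 treated arrays), PIK3IP1, an inhibitor of PI3 kinase, by 3.48 and KLF2 by 3.04. Without treated replicate 1 the rise of P2RY14 was 4.25 (19-fold, adjusted p = 3e-10). P2RX5, an ATP-gated channel, rose by 3.40. The largest falls were in LYZ, lysozyme, at -1.94 (SE 0.15, adjusted p = 1.7e-07), GCNT1 at -1.56 and FAM111B at -1.46, with ID3 at -1.43, UNG at -1.38 and MYC at -0.96. BCL2 was at -0.82 (adjusted p = 0.025), a call that ended without untreated replicate 1 (-0.64) or 4 (-0.84) or treated replicate 2 (-0.73), 3 (-0.76) or 4 (-0.70), and with the mean of its probe sets (-0.25, adjusted p = 0.054) or these groups alone (adjusted p = 0.14).

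Of the 44 glucocorticoid-induced genes, 24 rose and 2 fell in cells labelled CASP1 (26 and 2 adjusted over the list alone, mean 0.919, adjusted p = 5.03e-25), and this list also passed with an estimated correlation (adjusted p = 0.000503). DNA replication genes fell in 22 of 39 cases and rose in 0 (28 falling adjusted over the list alone, mean -0.46, adjusted p = 1.63e-26, and adjusted p = 0.0538 with an estimated correlation), with MCM10 at -0.88 and MCM4 at -0.81. Of the 35 MYC and nucleolar genes 8 fell and 0 rose (12 falling adjusted over the list alone, mean -0.261, adjusted p = 8.84e-10, and adjusted p = 0.208 with an estimated correlation). Autophagy and FOXO targets had 7 rising and 1 falling (11 and 2 adjusted over the list alone, mean 0.445, adjusted p = 3.6e-06, and adjusted p = 0.0853 with an estimated correlation), with TXNIP at 1.19 and FBXO32, an atrophy-related ubiquitin ligase, at 1.07. Antigen presentation had 3 rising and 1 falling (10 and 1 adjusted over the list alone, mean 0.314, adjusted p = 0.00118, and adjusted p = 0.421 with an estimated correlation).

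A further 3 lists passed in cells labelled CASP1 with the preset correlation and depended on single arrays or on replicate 1. Replication-dependent histones had 3 of 17 rising (5 adjusted over the list alone, mean 0.281, adjusted p = 0.00111, and adjusted p = 0.208 with an estimated correlation), and the mean was 0.154 with adjusted p = 0.11 without the 4 arrays of replicate 1. The p53 targets had 3 of 25 rising (4 adjusted over the list alone, mean 0.215, adjusted p = 0.0453, and adjusted p = 0.795 with an estimated correlation). The p53 mean was 0.11 without treated replicate 1 and 0.169, 0.177 and 0.193 without untreated replicates 2, 3 and 4, with adjusted p over 0.05 each time, and also without the dimmest 30% of genes (0.225, adjusted p = 0.067) or the 4 arrays of replicate 1 (0.215, adjusted p = 0.059). In control cells the p53 list did not pass (4 rising and 2 falling, mean 0.202, adjusted p = 0.322) but passed without those 4 arrays (0.281, adjusted p = 0.027). ATF4 and amino acid response genes had 5 of 33 falling and 1 rising, as adjusted over the list alone (mean -0.138, adjusted p = 0.00954, and adjusted p = 0.81 with an estimated correlation). The ATF4 mean was -0.247 without treated replicate 1 and -0.251 without the 4 arrays of replicate 1, and the call ended without treated replicate 2 (-0.082) or 4 (-0.105) or when the arrays were quantile normalized again (-0.113, adjusted p = 0.065).

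In this line 1150 genes were called for prednisolone in limma's test, 542 higher and 608 lower, with 153 at least 2-fold higher and 17 at least 2-fold lower. The G2 and mitosis list did not pass (mean -0.0464, adjusted p = 0.135) but had a mean of -0.129 with adjusted p = 2.9e-05 without the 4 arrays of replicate 1 and of -0.161 without treated replicate 1 alone. The glycolysis and hypoxia list did not pass either (mean -0.13, adjusted p = 0.135), but passed without those 4 arrays (-0.168, adjusted p = 2.7e-06), with a batch term for them (adjusted p = 0.0011), without untreated replicate 1 (-0.299) and without treated replicate 3 (-0.199). Cholesterol biosynthesis likewise did not pass (mean -0.0806, adjusted p = 0.0784) but passed without those 4 arrays (-0.0692, adjusted p = 0.021), with the batch term (adjusted p = 0.027), without untreated replicate 1 (-0.101) and without treated replicate 3 (-0.105). Without those 4 arrays the count of genes was 2161, and with only the 8 arrays of this line in the model it was 688.

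The responses of the 2 lines overlapped. Of the 542 genes that rose in cells labelled CASP1, 392 (72.3%) also rose in control cells, where independent lists would share 31.1, and of the 608 that fell, 450 (74%) also fell, where independent lists would share 51.3. Only 2 genes were called in opposite directions. Both tests used the same residual spread of each gene, which can raise the overlap above that of independent lists. Across all 18132 genes, which are not independent replicates, the responses correlated with r = 0.725.

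The interaction asked whether the prednisolone response differed between the lines, with the response on the arrays labelled CASP1 taken minus that of control cells. P2RY14 rose less in cells labelled CASP1 by -3.98 (SE 0.66, adjusted p = 0.0056), LILRB2 by -2.98 (SE 0.18, adjusted p = 8.6e-08), both from untreated signals near the floor that leave the size uncertain, TP53INP1 by -2.81 and TXNIP by -2.63 (SE 0.17, adjusted p = 1e-07). Without replicate 1 of the treated cells labelled CASP1 the value for P2RY14 was -3.24 (adjusted p = 4e-06). Of the 2 TP53INP1 probe sets, 1 had the sign of this interaction and 0 were called in the opposite direction. For TXNIP the untreated signal was already 3.22 higher in cells labelled CASP1. BCL2 fell less in these cells, with an interaction of 1.63 (SE 0.30, adjusted p = 0.012), and its untreated signal was lower there by -1.87. SKP2 also fell less (1.23, SE 0.15, adjusted p = 0.00048). TSC22D3 (1.09, adjusted p = 0.0071) and P2RX5 (1.48, adjusted p = 0.014) rose more in cells labelled CASP1. For TSC22D3 the untreated signal was lower there, at 6.887 against 7.802 in control cells, while the treated signals were close, at 12.67 against 12.5.

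Lists differed in the interaction as well. Of the 39 DNA replication genes, 9 had an interaction above 0 over all genes and 31 adjusted over the list alone (mean 0.505, adjusted p = 1.78e-27), which is a smaller fall in cells labelled CASP1, with GINS2 at 1.03 and RFC5, a clamp loader subunit, at 0.89. Antigen presentation had 1 gene below 0 over all genes and 11 adjusted over the list alone (mean -0.467, adjusted p = 5.84e-12). Autophagy and FOXO targets had 3 and 6 below 0 (mean -0.284, adjusted p = 1.62e-07), and endoplasmic reticulum chaperones 0 and 6 (mean -0.26, adjusted p = 3.22e-08). These 4 lists also passed with an estimated correlation. The MYC and nucleolar list had 0 genes called over all genes and 1 above 0 adjusted over the list alone (mean 0.224, adjusted p = 1.3e-05, and adjusted p = 0.318 with an estimated correlation), and its mean was 0.139 (adjusted p = 0.0089) without the 4 arrays of replicate 1. The glucocorticoid-induced list had 2 above 0 and 3 below (5 and 10 adjusted over the list alone, mean -0.181, adjusted p = 0.000521, and adjusted p = 0.123 with an estimated correlation). G2 and mitosis had 1 gene above 0 (4 adjusted over the list alone, mean 0.286, adjusted p = 2.68e-07, and adjusted p = 0.234 with an estimated correlation), and its mean was 0.171 without replicate 1 of the treated cells labelled CASP1, as without the 4 arrays of replicate 1. Cholesterol biosynthesis had 1 gene above 0, as adjusted over the list alone (mean 0.173, adjusted p = 0.00356, and adjusted p = 0.117 with an estimated correlation).

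The remaining 3 lists called for the interaction lost their call without single arrays. NF-kappaB targets had a mean of -0.101 (adjusted p = 0.0302, and adjusted p = 0.123 with an estimated correlation) with 0 members called over all genes or adjusted over the list alone, as for the other lists of this paragraph. That call ended without replicate 1 (-0.0729) or 2 (-0.0959) of untreated control cells, replicate 1 of treated control cells (-0.102) or replicate 2 of treated cells labelled CASP1 (-0.0854), and without the 4 arrays of replicate 1 (-0.0624). It also ended without the dimmest 30% of genes (-0.133, adjusted p = 0.058) and with the mean of each gene's probe sets (-0.0462, adjusted p = 0.18). The respiratory chain had a mean of 0.129 (adjusted p = 0.0173, and adjusted p = 0.402 with an estimated correlation), a call that ended without replicate 1 of untreated control cells (0.105), replicate 3 of treated control cells (0.107) or replicates 1 (0.108) or 2 (0.12) of treated cells labelled CASP1. Heat shock and receptor chaperones had a mean of 0.255 (adjusted p = 0.0173, and adjusted p = 0.163 with an estimated correlation). That call ended without replicate 2 of untreated control cells (0.243), replicate 1 of treated control cells (0.229) or replicate 1 of treated cells labelled CASP1 (0.214), and with the mean of each gene's probe sets (0.227, adjusted p = 0.064). Without the 4 arrays of replicate 1 together the respiratory chain call (0.127, adjusted p = 0.017) and the heat shock call (0.212, adjusted p = 0.0071) were kept.

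**Figure D2:**
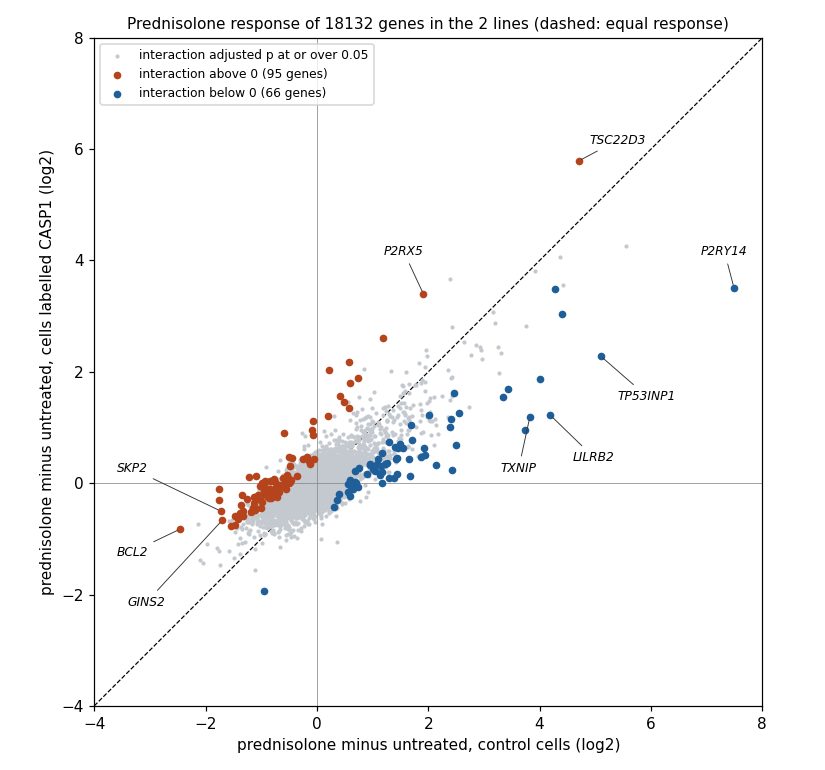
Log2 prednisolone response of 18132 genes (points) in control cells (x axis) against cells labelled CASP1 (y axis), with the dashed line at equal response and the 161 genes called for the interaction in colour, 95 above 0 in red and 66 below 0 in blue. P2RY14 lies at 7.49 and 3.51, TSC22D3 at 4.70 and 5.79 and BCL2 at -2.46 and -0.82.

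The interaction called 161 genes in limma's test, and 1871 had an unadjusted p under 0.05. Of the 161, 138 (85.7%) had the smaller absolute response in cells labelled CASP1, 112 of them with the same sign in both lines, and 23 had the larger one. Simulated data with equal responses gave 50.1% (20 draws), a share that follows from the symmetry of the simulated noise. Of the 161 genes, 150 were called for prednisolone in control cells, 70 in cells labelled CASP1 and 59 in both. The count of 161 was 268 without replicate 1 of treated cells labelled CASP1, 96 without replicate 4 and 102 without replicate 3 of treated control cells, 103 and 102 without replicates 3 and 4 of untreated control cells, 99 and 98 without replicates 2 and 3 of untreated cells labelled CASP1, and 727 without the 4 arrays of replicate 1. For genes selected in control cells on separate arrays, the mean response in cells labelled CASP1 was 0.603 of that in control cells (range 0.541 to 0.70 over 6 choices of arrays, 299 to 3110 genes). The ratio was 0.652 to 0.70 in the 3 choices that selected on replicate 1 (299 to 435 genes) and 0.541 to 0.555 in the 3 that did not (2100 to 3110 genes). The ratio depended on the genes taken, since it was 0.835 for the fixed glucocorticoid-induced list and 0.922 for genes selected in cells labelled CASP1.

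Untreated cells of the 2 lines differed in many genes besides CASP1, with the label of the lines going against the CASP1 signal. ARMCX5 was 36.3-fold higher on the arrays labelled CASP1 (log2 5.18, SE 0.14, n = 4, adjusted p = 1e-13), from a signal near the floor in control cells. PRPS2, an enzyme of nucleotide precursor synthesis, was higher by 3.31, TXNIP by 3.22, CD59, an inhibitor of complement, by 2.86 and TP53INP1 by 2.25. For TP53INP1, 1 of its 2 probe sets had this sign. MTFR2, a regulator of mitochondrial fission, was lower at -2.52 (SE 0.08, 5.74-fold), and CMPK2, a mitochondrial nucleotide kinase, was at -2.33. IL1B, whose product CASP1 cleaves, was at -1.88, BCL2 at -1.87 and IL7R, a receptor for a growth factor of B-cell precursors, at -1.85.

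Of the 35 genes of MYC and nucleolar ribosome biogenesis, 27 were lower and 0 higher in untreated cells labelled CASP1 (30 lower adjusted over the list alone, mean -0.601, adjusted p = 3.78e-23), including RRS1 at -1.10, PPAN at -1.09 and ODC1 at -1.08. Of 35 genes of G2 and mitosis, 25 were higher and 0 lower (30 higher adjusted over the list alone, mean 0.575, adjusted p = 9.58e-21), including MKI67 at 1.59 and KIF20A at 1.42. Autophagy and FOXO targets had 13 higher and 1 lower of 29 (15 and 1 adjusted over the list alone, mean 0.428, adjusted p = 6.82e-09). These 3 lists also passed with an estimated correlation. Histones had 7 of 17 higher, as adjusted over the list alone (mean 0.497, adjusted p = 1.51e-05, and adjusted p = 0.0515 with an estimated correlation), with H2BC12 at 1.72 (SE 0.0925). The p53 targets had 10 higher and 1 lower of 25 (11 and 1 adjusted over the list alone, mean 0.412, adjusted p = 2.77e-05, and adjusted p = 0.225 with an estimated correlation). DNA replication genes had 15 lower and 1 higher of 39 (19 and 2 adjusted over the list alone, mean -0.217, adjusted p = 1.56e-05, and adjusted p = 0.458 with an estimated correlation), with MCM4 at -0.65. Endoplasmic reticulum chaperones had 7 of 21 lower, as adjusted over the list alone (mean -0.233, adjusted p = 0.00151, and adjusted p = 0.0515 with an estimated correlation), with SDF2L1 at -0.87.

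For 3 lists the untreated difference depended on single arrays. Glycolysis and hypoxia genes had 5 lower and 1 higher of 27 (7 and 1 adjusted over the list alone, mean -0.365, adjusted p = 0.00525, and adjusted p = 0.682 with an estimated correlation). The glycolysis mean was -0.195 with adjusted p = 0.18 without replicate 1 of untreated cells labelled CASP1 and -0.55 without replicate 1 of untreated control cells. It was -0.38 with adjusted p = 2e-06 without the 4 arrays of replicate 1, which were low for this list in both untreated groups. Heat shock and receptor chaperones had 6 of 18 lower (7 adjusted over the list alone, mean -0.138, adjusted p = 0.0297, and adjusted p = 0.225 with an estimated correlation), and the call ended without replicate 2 of untreated control cells (-0.126) and with the mean of each gene's probe sets (-0.0979, adjusted p = 0.057) or a batch term for replicate 1 (adjusted p = 0.056). It was kept without the 4 arrays of replicate 1 (-0.161, adjusted p = 0.019). ATF4 and amino acid response genes had 3 of 33 lower (2 adjusted over the list alone, mean -0.152, adjusted p = 0.0321, and adjusted p = 0.849 with an estimated correlation). That mean turned to 0.027 without replicate 1 of untreated control cells, was -0.148 with adjusted p = 0.071 without replicate 1 of untreated cells labelled CASP1, and was 0.0311 without the 4 arrays of replicate 1. The ATF4 call also ended when the arrays were quantile normalized again (-0.121, adjusted p = 0.066) and without the dimmest 30% of genes (-0.159, adjusted p = 0.095). In limma's test 2552 genes were called between the untreated lines, 1065 higher and 1487 lower, and 3876 were called without the 4 arrays of replicate 1.

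In prednisolone-treated cells the lines differed again, and the label again went against the CASP1 signal. ARMCX5 (4.46), PRPS2 (2.99) and CD59 (2.55) were higher in cells labelled CASP1. P2RY14 was 23.5-fold lower (log2 -4.55, SE 0.47, n = 4, adjusted p = 3.9e-06), SH3BP2, an adaptor of immune receptor signalling, was at -3.44 and LILRB2 at -3.21. Without replicate 1 of the treated cells labelled CASP1 the difference in P2RY14 was -3.82 (14.1-fold lower, adjusted p = 1.4e-09). The pore-forming protein gene GSDME, which prednisolone raised by 3.75 in control cells, was at -2.01, with an interaction of -0.93 that did not pass (adjusted p = 0.27).

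Of 35 genes of G2 and mitosis, 31 were higher and 0 lower in treated cells labelled CASP1 (33 higher adjusted over the list alone, mean 0.861, adjusted p = 7.27e-28), with MKI67 at 1.79 and AURKA at 1.35. Endoplasmic reticulum chaperones had 14 of 21 lower and 0 higher (15 lower adjusted over the list alone, mean -0.493, adjusted p = 7.27e-12), with HSPA5 at -1.19. Histones had 9 of 17 higher (10 adjusted over the list alone, mean 0.565, adjusted p = 6.57e-07). These 3 lists also passed with an estimated correlation. DNA replication genes had 15 higher and 1 lower of 39 (23 and 2 adjusted over the list alone, mean 0.288, adjusted p = 2.21e-06, and adjusted p = 0.381 with an estimated correlation), with CDT1, a licensing factor, at 1.17. The MYC and nucleolar list had 17 of 35 lower (22 adjusted over the list alone, mean -0.377, adjusted p = 7.27e-12, and adjusted p = 0.133 with an estimated correlation), with RRS1 at -0.94. Antigen presentation had 11 lower and 2 higher of 23 (14 and 2 adjusted over the list alone, mean -0.586, adjusted p = 8.16e-08, and adjusted p = 0.133 with an estimated correlation), with CIITA at -2.18 and HLA-DQA1 at -2.02. The p53 targets had 10 higher and 1 lower of 25 (10 and 2 adjusted over the list alone, mean 0.426, adjusted p = 0.000103, and adjusted p = 0.33 with an estimated correlation), with CDKN1A, a cell cycle inhibitor, at 1.58 and DDB2 at 1.39.

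Pre-B cell identity genes had 11 lower and 1 higher of 39 in treated cells labelled CASP1 (13 and 1 adjusted over the list alone, mean -0.195, adjusted p = 0.000628, and adjusted p = 0.378 with an estimated correlation), and the mean was -0.12 without replicate 1 of that group and -0.129 without the 4 arrays of replicate 1. Cholesterol biosynthesis had 6 of 24 higher, as adjusted over the list alone (mean 0.138, adjusted p = 0.0335, and adjusted p = 0.284 with an estimated correlation), and the call ended without replicates 3 (0.114) or 4 (0.128) of that group or with a batch term for replicate 1 (adjusted p = 0.055). The glycolysis and hypoxia list did not pass between the treated lines (mean -0.241, adjusted p = 0.218) but passed without the 4 arrays of replicate 1 (-0.27, adjusted p = 0.00034), with the batch term (adjusted p = 0.00087) and without replicate 1 of treated control cells (-0.402, adjusted p = 0.015). The glucocorticoid-induced list did not differ past the threshold between the lines, with means of 0.142 untreated (adjusted p = 0.0841) and -0.0393 treated (adjusted p = 0.709). The untreated difference passed without replicate 1 of cells labelled CASP1 (0.151, adjusted p = 0.041) or replicate 4 of control cells (0.165, adjusted p = 0.041). In limma's test 2974 genes were called between the treated lines, 1429 higher and 1545 lower. Of the genes higher in treated cells labelled CASP1, 589 were also higher without treatment, where independent lists would share 83.9, and of those lower, 863 were also lower, where independent lists would share 127. The shared residual spread of each gene can raise these overlaps too.

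Another 10 lists were called in none of the 5 comparisons. The inflammasome and pyroptosis list had 24 measured genes and adjusted p between 0.287 and 0.936, and the BCL2 family had 16 and adjusted p between 0.322 and 0.997. Interferon-stimulated genes (35, lowest adjusted p 0.0732), MAPK feedback genes (25, 0.267), cytosolic ribosomal proteins (35, 0.362) and the plasma cell programme (11, 0.553) did not pass either. With a batch term for replicate 1 the interferon list passed between the treated lines (mean -0.18, adjusted p = 0.041), as it did without replicate 3 (-0.196) or 4 (-0.19) of treated control cells, and with the mean of each gene's probe sets the ribosomal protein list passed for prednisolone in cells labelled CASP1 (mean 0.0708, adjusted p = 0.013). The markers of other cells did not pass, with lowest adjusted p values of 0.287 for stromal and epithelial cells, 0.714 for T and natural killer cells, 0.749 for myeloid cells and 0.883 for erythroid cells and megakaryocytes.

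**Figure D3:**
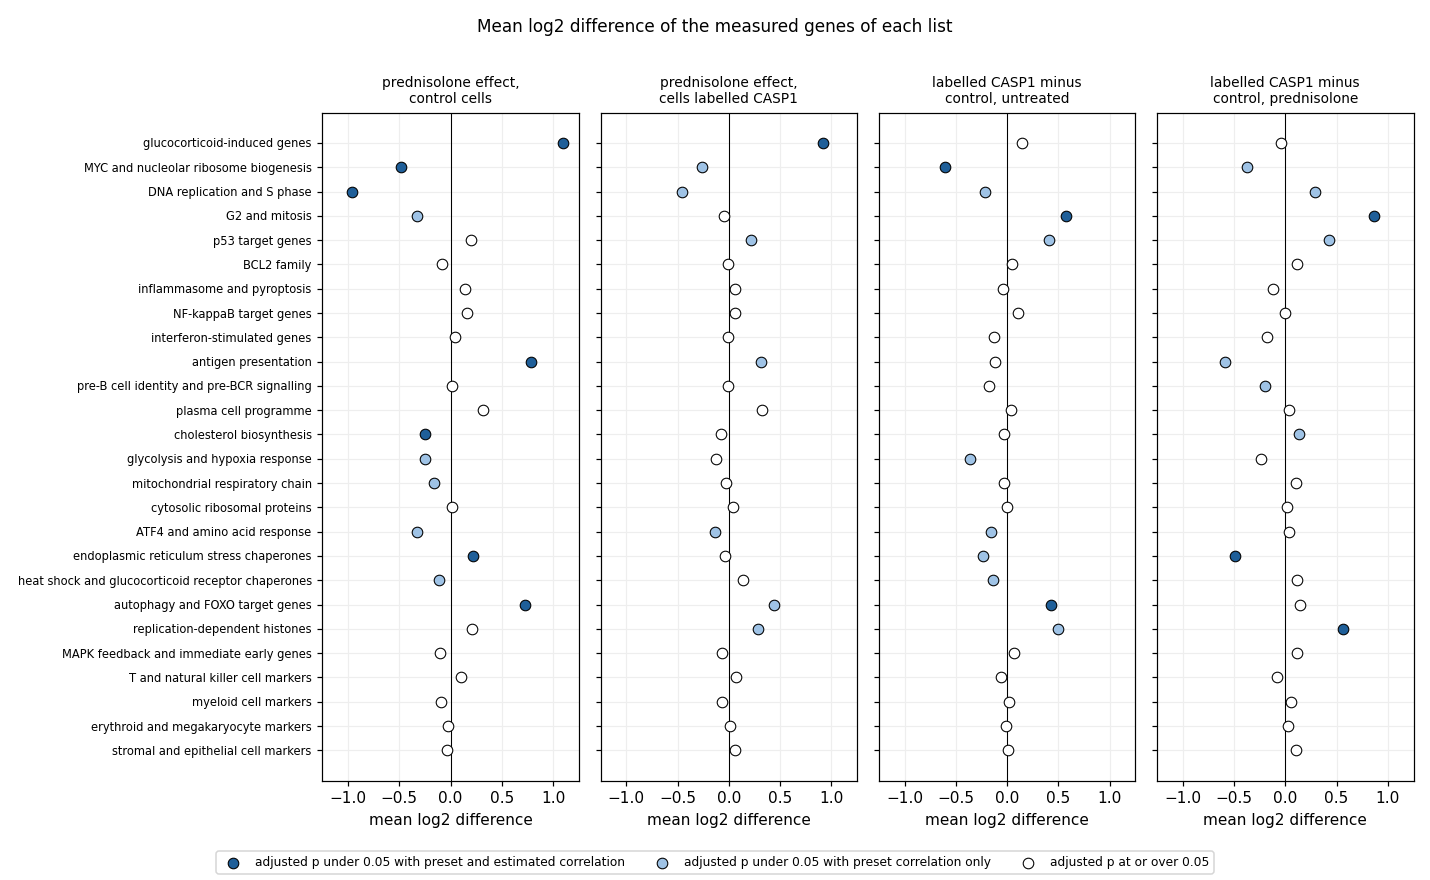
Mean log2 difference (x axis) of the measured genes of each of the 26 lists (y axis) in the 4 comparisons named above the panels, dark where the list passed with the preset and the estimated correlation, light where it passed with the preset one only and open where it did not pass. DNA replication genes had means of -0.965 for prednisolone in control cells and -0.46 in cells labelled CASP1.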

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

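The tests of the hybridisation controls, of introduced CASP1 RNA and of regional loss as the whole CASP1 difference were chosen after the results were seen, and so was the removal of the 4 arrays of replicate 1. The others were chosen before.

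CASP1 signal was lower, by -2.06 in untreated cells, on the arrays whose label says it was overexpressed. Loss or silencing of a region that reaches the 10 neighbours taken is argued against as the whole of this. Their median difference was -0.27 (SE 0.17) and the lowest was -0.53. They were the nearest of the brighter genes and include the related caspase gene CASP4 at -0.4, and their sequences were not compared with CASP1. A loss confined to CASP1 and dimmer genes beside it was not probed. A smaller regional fall stays open, since 3 of these neighbours were called lower (DCUN1D5 at -0.24, MSANTD4 at -0.48 and AASDHPPT at -0.53) and 1 higher (KBTBD3 at 0.6), and the median lay within its SE of the -0.3 set beforehand. Introduced RNA that the probes cannot read would leave the signal unchanged, so it is argued against as the reason for the fall by the 7 CASP1 probe sets above background, of which the least changed differed by -1.7 in untreated cells. An exchange of the 2 line labels needs neighbours within 0.3 of 0, which the median met by less than its SE, so it, a smaller regional fall and a lower endogenous CASP1 in a derived line, which was not tested, cannot be told apart.

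The test of the difference between the lines' prednisolone responses marked 161 genes. For a test by exchange, the mean difference between the lines was first taken out of each gene. Of 100 drawn exchanges of the line labels within a treatment 1, the real one, gave as many, and the highest of the others gave 0. This argues against a chance arrangement of the arrays. The other exchanges mix the lines, which turns a real difference in response into spread within groups, so low counts there were likely. With 1 line per label, the exchanges cannot tell a chance difference between lines from an effect of the label. The smaller response in cells labelled CASP1 could come from the replicate 1 arrays or from compression of bright signals. Without those arrays the median ratio was 0.592, and 0.601 at most, against 0.603 over all 6 choices with them. A ratio under 1 thus did not need them. The 3 choices that select on other replicates gave 0.541 to 0.555 with replicate 1 among the measuring arrays. Leaving it out therefore raised the ratio a little for these selections. The ratio was 0.563 in the dimmer part of the genes against 0.644 in the brighter part, so the dimmer part did not have the higher ratio. These genes were selected in control cells, which favours genes that respond more there, and the ratio was higher for genes selected in cells labelled CASP1. A ratio under 1 therefore does not by itself show a smaller response. Untreated levels already shifted in the direction of the prednisolone effect may account for part of it, at a share of the missing response of 0.364 in the planned choice of arrays, against the 0.5 set beforehand as what that explanation needs, and of 0.323 to 0.364 in the 3 choices that select on replicate 1 and 0.576 to 0.646 in the 3 that measure on it, so this and a biological effect of the line cannot be told apart. The share was 0.559 to 1.08 for genes that fell, above 0.5 in all 6 choices, and 0.0864 to 0.351 for genes that rose. By construction the missing response is the signed untreated difference between the lines minus the treated one. The share therefore shows where that difference lies, not its cause. Because the CASP1 signal goes against the label, none of these values tie the smaller response to more CASP1.

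The genes with the largest positive values in that test were FUT7 at 1.82, CAPSL at 1.64, BCL2 at 1.63, RNF166 at 1.59, BCL6 at 1.49, P2RX5 at 1.48, GLDC at 1.45, PIEZO1 at 1.41, KCNMB3 at 1.34, SKP2 at 1.23, DDIT4L at 1.22 and HSPA6 at 1.2. For BCL6, DDIT4L, KCNMB3 and HSPA6 the mean fell in control cells only, by little for HSPA6 (4.287 to 4.212). The others had a smaller fall or a larger rise in cells labelled CASP1. The largest negative values were those of P2RY14 at -3.98, LILRB2 at -2.98, TP53INP1 at -2.81, DAPL1 at -2.8, TXNIP at -2.63, GPR171 at -2.2, TDRD9 at -2.14, CHRNA1 at -1.81, LILRB1 and SH3BP2 at -1.8 each, CSGALNACT1 at -1.74 and RNASE6 at -1.54. For TP53INP1, 1 of its 2 probe sets had this sign. The call ended without any 1 of 12 arrays for FUT7 (adjusted p up to 0.11), 14 for BCL6 (0.12), 9 for CHRNA1 (0.087), 6 for HSPA6 (0.059) and 5 for DDIT4L (0.072) among the 16, and P2RY14 was at -3.24 without replicate 1 of treated cells labelled CASP1. CAPSL was at 4.634 in untreated control cells and at 2.733 in untreated cells labelled CASP1, near the lowest signals. The floor left it no room to fall there, so its value says nothing about a smaller response. KCNMB3 was at 3.699 in untreated cells labelled CASP1, already below the 3.989 of treated control cells, so it may have had little room to fall. The sizes and ranks of FUT7, P2RY14, LILRB2, GPR171, TDRD9 and LILRB1 are uncertain because their untreated means of 2.508 to 3.458 also lay near the floor. The calls of FUT7 and BCL6 also ended with quantile normalization again (adjusted p = 0.063 and 0.06), the 75th percentile (0.05 and 0.052) and trend with robust settings (0.071 and 0.055), and that of BCL6 with the mean of its probe sets (0.904, adjusted p = 0.14).

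The lists whose responses differed were DNA replication and S phase at 0.505, antigen presentation at -0.467, G2 and mitosis at 0.286, autophagy and FOXO target genes at -0.284, endoplasmic reticulum stress chaperones at -0.26, heat shock and glucocorticoid receptor chaperones at 0.255, MYC and nucleolar ribosome biogenesis at 0.224, glucocorticoid-induced genes at -0.181, cholesterol biosynthesis at 0.173, mitochondrial respiratory chain at 0.129 and NF-kappaB target genes at -0.101. Of these 11, only DNA replication, antigen presentation, autophagy and FOXO targets and the endoplasmic reticulum chaperones also passed with an estimated correlation. For the others adjusted p with an estimated correlation was 0.234 for G2 and mitosis, 0.163 for heat shock, 0.318 for MYC, 0.123 for the glucocorticoid-induced list, 0.117 for cholesterol, 0.402 for the respiratory chain and 0.123 for NF-kappaB. The heat shock, respiratory chain and NF-kappaB calls also ended without single arrays, as without replicate 1 of treated cells labelled CASP1 for heat shock (0.214) and the respiratory chain (0.108) and without replicate 1 of untreated control cells for NF-kappaB (-0.0729).

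The other counts of called genes were each set against the 35 splits of the 8 arrays compared, of which 1, the real one, gave as many. The real count and the highest of the others were 2568 and 2 for prednisolone in control cells and 1150 and 3 in cells labelled CASP1. They were 2552 and 1 between the untreated lines and 2974 and 25 between the treated lines. This argues against a chance arrangement of the arrays, though 35 splits cannot give a share under 1 in 35. Every other split mixes arrays of both groups, so low counts there were likely. With 1 line per label, the splits cannot tell chance differences between cultures or lines from an effect of treatment or label.

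Chance sets any 1 of the 4 arrays of a set apart in about 1 in 20 sets, and a given array in fewer. Replicate 1 lay far from the other 3 arrays in a larger share of genes than 1 in 20 in every group. The same held for lists in every group but treated cells labelled CASP1, where it was 1 of 26. Among 272 sets of 4 arrays for 68 named genes, 46 had an array set apart from the others, 41 of them replicate 1, at 9 genes in untreated control cells, 11 in treated control cells, 10 in untreated cells labelled CASP1 and 11 in treated ones. Replicate 1 had the lowest hybridisation controls in 3 of the 4 groups, lower by -0.32 in the mean over all 4, but the fourth group did not show it. These controls were read after RMA had brought the arrays to a common scale, so they give levels relative to the other signals. They cannot show weaker hybridisation or labelling of a whole array. These causes and a separate culture or day cannot be told apart. RNA degradation is argued against, since the excess of 3 prime over 5 prime signal in replicate 1 was 0.056 in the mean and 0.11 at most. Each group holds 1 such array, and without these 4 arrays the counts of called genes were higher in all 5 comparisons, as with 3969 against 2568 genes for prednisolone in control cells.

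Single genes set apart elsewhere were 1 in replicate 2 and 1 in replicate 3 of untreated cells labelled CASP1, 2 in replicate 3 of untreated control cells and 1 in replicate 4 of treated cells labelled CASP1. Of 104 sets of 4 arrays for the gene lists, 14 had an array set apart, 13 of them replicate 1, with 5 lists in untreated control cells, 3 in treated control cells, 4 in untreated cells labelled CASP1 and 1 in treated ones, and 1 list in replicate 2 of treated cells labelled CASP1. The glycolysis and hypoxia list was lower in replicate 1 in 3 groups, with 8.61 against a mean of 9.35 on the other arrays of untreated control cells. The ATF4 and amino acid response list was higher there, at 9.39 against 8.67. In treated cells labelled CASP1 the G2 and mitosis list was at 10.3 in replicate 1 against 9.85.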

How the results depend on the processing

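Leaving out the 4 arrays of replicate 1 and a batch term for them were chosen after seeing the data. Where a count or value changed, the cause was not tested, except that stricter thresholds, single probe sets and fewer arrays change counts by construction. Counts are given for prednisolone in control cells, prednisolone in cells labelled CASP1, the untreated lines, the treated lines and the interaction in that order, from 2568, 1150, 2552, 2974 and 161. Quantile normalization again, the 75th percentile, filters on dim genes, the mean of a gene's probe sets and trend with robust settings kept all 5 counts within 1.5 times, and no scaling moved the share of higher calls by over 10 percentage points. Of 396 named gene results that were called, 0 reversed in any alternative and 52 lost the call without 1 array, and the mean of a gene's probe sets ended 38 calls. Signals near the floor limit what can be seen, since a fold from there is compressed by background.

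Every probe set on its own gave 6065, 2558, 5911 and 7197 called probe sets before the interaction. Array weights gave 4557, 2322, 4505, 4469 and 863. An adjusted p under 0.01 gave 1669, 572, 1445, 1637 and 53, and a change of at least 1.5-fold gave 1124, 469, 987 and 1095 for the first 4. With only the 8 arrays of the comparison, the second count was 688. Without the 4 arrays of replicate 1 the counts were 3969, 2161, 3876, 4062 and 727, and with the batch term the second and last were 1793 and 392.

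The replicate numbers were not taken to pair the arrays, since that needed a correlation over 0.1 between the deviations of all 24 pairs of arrays with the same number, and 15 reached it. The arrays of replicate 1 did deviate together (0.19 to 0.51), while those of replicates 2 to 4 lay between -0.12 and 0.26, and between the untreated lines all 4 pairs were over 0.1 (0.15 to 0.43). In all, 8 of 16 arrays were closest to one of their own number. This count includes the replicate 1 arrays, whose common deviation can raise it, so it does not show a pairing of the other arrays. With a replicate block the counts were 3174, 1559, 3213, 3819 and 289, and the block in the selecting fit gave a ratio of 0.581. The block ended the BCL6 call in the interaction (adjusted p = 0.063), the heat shock call between the untreated lines (0.059) and the cholesterol call between the treated lines (0.06). It added calls for glycolysis (0.0012) and cholesterol (0.024) for prednisolone in cells labelled CASP1, for glycolysis (9e-04) and interferon (0.041) between the treated lines and for the ATF4 list in the interaction (0.032).

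Leaving out each array in turn gave 2035 to 2556, 791 to 1292, 1985 to 2369, 2244 to 2877 and 96 to 268 genes, and a ratio of 0.586 to 0.635. The ratio of 0.603 was 0.835 for the fixed glucocorticoid-induced list and 0.922 for genes selected in cells labelled CASP1. With an estimated correlation 7, 1, 3, 3 and 4 lists were called, from 12, 8, 10, 9 and 11. The ATF4 and amino acid response list reversed between the untreated lines, from -0.152 to 0.0311 without the 4 arrays of replicate 1, and ranged from -0.22 to 0.027 with each array left out, the latter without replicate 1 of untreated control cells. Without the 4 arrays it also turned from 0.0384 to -0.0917 between the treated lines, where it was then called (adjusted p = 0.039). In the interaction its 0.191 did not pass (adjusted p = 0.0551), and alternatives called it in both directions. It was called above 0 with quantile normalization again (adjusted p = 0.041), without the dimmest 30% of genes (0.043), with the mean of a gene's probe sets (0.039), with the batch term (0.024) and without any 1 of 8 arrays, as with 0.259 without replicate 2 of untreated control cells. It was called below 0 without the 4 arrays of replicate 1 (-0.123, adjusted p = 0.00021).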

Other observations

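ARRDC4 was chosen after its values were seen, while the other genes named here follow the naming rule, and the test of neighbouring genes was planned.

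IL7R and IRF8 responded more to prednisolone in cells labelled CASP1, where their untreated signal was lower, while the pre-B cell list that holds both did not pass in the interaction (mean -0.0222, adjusted p = 0.234). IL7R, a receptor for a growth factor of B-cell precursors, was 1.85 lower there, with 9.97 in untreated control cells and 8.12 in untreated cells labelled CASP1, and rose with prednisolone by 1.56 (adjusted p = 1.45e-09) against 0.41 in control cells (interaction 1.15, adjusted p = 8.33e-05). IRF8, a transcription factor of B-cell and myeloid development, was 0.79 lower in untreated cells labelled CASP1 (adjusted p = 0.000659) and rose by 1.88 against 0.74 (interaction 1.14, adjusted p = 0.00713). TXNIP, 3.22 higher in untreated cells labelled CASP1, had a higher relative in the same family, ARRDC4, at 1.70 (adjusted p = 3.56e-08), and both are known targets of the glucose-sensing factor MLXIP.

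The histone gene H2BC12 was higher by 1.72 in untreated and 1.36 in treated cells labelled CASP1. H2BC21, of the same list, rose with prednisolone by 1.55 in control cells (adjusted p = 2.65e-07), where the list did not pass (adjusted p = 0.103). Without the dimmest 30% of genes the list passed there (mean 0.334, adjusted p = 0.035). GZMK, a granule protease of lymphocytes, rose with prednisolone by 2.72 in control cells (adjusted p = 1.65e-06), and the interferon-inducible MX1 rose by 1.65 and 1.78 in control cells and cells labelled CASP1. The interferon-stimulated list did not pass for prednisolone in either line. It had 5 genes rising and 4 falling in control cells, and 2 rising and 3 falling in cells labelled CASP1.

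Lines grown apart may differ in copy number, which would make neighbouring genes differ together. Across 10869 genes, the difference between the untreated lines correlated between adjacent genes with r = 0.046, above the highest of 1000 random gene orders (0.031), but the prednisolone effect in control cells, which copy number cannot give, reached 0.1. Copy number and shared regulation of neighbours cannot be told apart by this value.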
